A study of Rattus norvegicus with 16 samples.

How the data were processed

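Total RNA from rat hearts was depleted of ribosomal RNA with a NEBNext kit and made into libraries with a NEBNext kit, per the labels' protocols. There were 16 libraries, 1 per animal: 5 WKY, 5 SHR and 6 SHR given neferine at 10 mg/kg per day for 10 weeks. Groups came from the labels. The replicate numbers are those in the titles. The labels name the rats by group and number, and each number was taken as a separate animal.

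The authors deposited 1 file per library with a transcript identifier and a normalised abundance signal on a linear scale. The values are decimal and not negative, do not sum to a fixed total, and show no step of whole reads at low values, so they were treated as neither counts nor a unit with a known total. Whether they are scaled by transcript length and library size or another abundance unit is not given in the sources used here, nor are the aligner, the quantification tool, the genome build and the annotation. The submitters' processing notes name limma without a version or a role. The identifiers are Ensembl rat transcripts and transcripts that begin with MERGE and carry a locus number and a transcript number, so transcripts were assembled and merged before the values were made.

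The rows had been filtered before deposit. In the WKY and SHR files every row had a WKY or SHR mean of at least 0.5. In the neferine files all 31042 rows shared with the others had a SHR or neferine mean of at least 0.5, and the lowest neferine mean among the 1556 rows of the neferine files alone was 0.5. Of the 1882 rows of the WKY and SHR files alone, 1788 had a SHR mean under 0.5, and 94 did not, so this filter does not account for all of them. A transcript present in WKY alone is therefore mostly missing from the shared rows. The depth of each library is unknown, and no counting interval was given. The number of animals sets the precision.

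The choice of tests was fixed before the data were examined. It planned a count model for counts and limma for normalised values, and the files hold normalised values. The test was limma 3.58.1 in R 4.3.3 with a variance trend, on log2(value + 1), over the 24577 of 31042 shared transcripts with a value of at least 1 in at least 5 libraries. All 16 libraries were in one fit with 1 mean per group and no covariate, and Benjamini-Hochberg adjusted p under 0.05 was the threshold. The comparisons were SHR against WKY, neferine-treated against untreated SHR, and neferine-treated SHR against WKY. A further result counted transcripts that passed the first and the second of these in opposite directions. Comparisons of a single value used exact permutation tests.

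The test was tried on simulated data with the spread of the real libraries. In these data 200 transcripts were changed by 1 or 2 on the log2 scale in either direction. They were drawn from transcripts with a mean log2(value + 1) of at least 2, so recovery at lower values was not simulated. For SHR against WKY the test recovered 65% of 100 transcripts changed by 1 and 83% of 100 changed by 2. There were 7 false calls among the unchanged transcripts. For neferine against SHR it recovered 67% and 84%, with 6 false calls. For neferine against WKY it recovered 71% and 80%, with 10 false calls.

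The rule for named items, also set beforehand, took genes with a symbol in each comparison, in the order of their fold change. They had to pass the threshold, have a mean of at least 1 in the higher group and not overlap between the groups. The rule also listed fixed genes by symbol and, where few passed, genes with the smallest unadjusted p. The reference table of the GRCr8 assembly pairs symbols with RefSeq accessions and matched 0 of the 31042 identifiers. For this reason the genes fixed by symbol and the 54 gene lists were not tested. The rule was narrowed once the identifiers were seen: the need for a symbol was dropped and fewer items were taken. Only 2 identifiers that rose and 2 that fell are given. None was chosen for neferine against WKY or by an unadjusted p.

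The alternatives were a pseudocount of 0.1, no filter on low values, fits of only the groups compared, the animal number as a block, stricter thresholds and the omission of each library. Alternatives chosen after the data were seen were other scalings, a covariate from the residuals, robust moderation, sums per assembled locus, other choices of rows and subsets of libraries. Correlations between comparisons that share a group were set against 50 simulations of unchanged groups and against 20 fits with the shared group split in 2 and 3. The count of calls in each of the 3 comparisons of groups was set against 99 other random splits of the same libraries. The count of transcripts moved back by neferine was not, and was set only against the simulations and the fits with split SHR libraries. For the placement of single libraries by strain, transcripts were called without the library concerned and its log2 value was compared with the mean of either strain.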

Results

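Ribosomal-RNA-depleted total RNA was sequenced from hearts of 16 rats in 3 groups. The spontaneously hypertensive rat (SHR) was compared with the Wistar Kyoto rat (WKY), the normotensive strain used as its control. A further group of SHR received neferine, an alkaloid of lotus seed, by stomach tube at 10 mg/kg per day for 10 weeks, while the other groups received distilled water. WKY and SHR had 5 animals each, and 6 SHR were given neferine. Per the labels, SHR were assigned at random to water or neferine. The files gave one normalised abundance per transcript and library, without read counts, so the sequencing depth is unknown. The deposited values summed to between 556993 and 663148 per WKY library, between 587365 and 683638 per SHR library, and between 611853 and 636768 per neferine library. The 10 most abundant transcripts of a library held between 30.2% and 44.3% of its sum.

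The WKY and SHR files listed 32924 transcripts and the neferine files 32598, of which 31042 were in both. Of the shared transcripts, 12553 carried Ensembl transcript identifiers and 18489 were transcripts assembled by the authors. Neither the files nor the reference table of gene symbols paired any of these identifiers with a gene name (0 matched), so results are given per transcript. No 2 libraries held identical values, and the highest Spearman correlation between 2 libraries over the shared transcripts was 0.755. A total of 24577 shared transcripts reached a value of 1 in at least 5 libraries and were tested. Fold changes are on the log2(value + 1) scale, which understates changes of transcripts with low values.

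The first principal component of the log2 values held 13.8% of the variance and separated all 5 WKY libraries from all 11 SHR libraries, treated or not. The second held 9.53%, and along it WKY 1, WKY 3, SHR 3 and SHR 4 lay apart from the other WKY and SHR libraries. The description of SHR 1 reads as WKY, whereas its title, strain, genotype and group fields read as SHR. Transcripts that differed between the strains were found again without each WKY or SHR library in turn, and the library left out was then placed by them. SHR 1 lay nearer to the mean of the other SHR libraries at 90.2% of 183 such transcripts. The other SHR libraries did so at 81.8% to 86.8%, and WKY libraries at 7.12% to 12.1%. Neferine libraries lay nearer to SHR at 86% to 90.3% of 513 transcripts. SHR 1 was therefore kept with the SHR group.

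**Figure D1:**
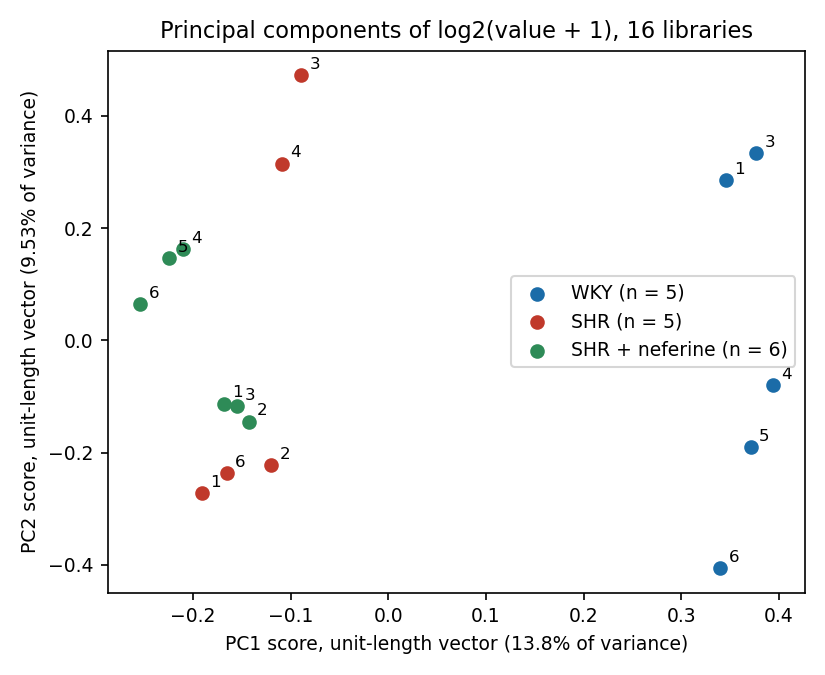
Scores of the 16 libraries on the first and second principal components of log2(value + 1) over 24577 transcripts, with colours for the 3 groups and replicate numbers beside the points. All WKY libraries have positive PC1 scores and all SHR and neferine libraries negative ones.

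The first comparison asked which cardiac transcripts differ between the hypertensive strain and its control. With limma (moderated variance with a trend, all 16 libraries in one fit, Benjamini-Hochberg adjusted p under 0.05), 720 of 24577 transcripts differed between SHR and WKY, which is 2.93% of those tested. Of these, 464 were higher and 256 lower in SHR. At an unadjusted p under 0.05, 2935 transcripts passed, against 1229 expected with no difference. The median absolute log2 fold change of the 720 transcripts was 1.14, and 422 of them had an absolute log2 fold change of at least 1. Among annotated transcripts 139 were higher and 121 lower, and among assembled transcripts 325 were higher and 135 lower. The values of the 5 SHR and 5 WKY libraries did not overlap for 626 of the 720. Across all tested transcripts, 4.45% did not overlap, against 0.794% by chance.

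The division into higher and lower transcripts changed with the rows tested. When only the WKY and SHR libraries were fitted, over all 32924 rows of their files, limma called 641 of 20746 transcripts at the same threshold, 337 higher and 304 lower in SHR. The same 10 libraries on the shared rows gave 513 of 20641, 319 higher and 194 lower. The share higher in SHR was 52.6% with all rows and 62.2% with the shared rows, against 64.4% in the fit of all 16 libraries on shared rows.

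Among the tested rows shared with the neferine files, and among transcripts whose libraries did not overlap, the largest rises in SHR were those of MERGE.6140.3 and MERGE.16966.1. MERGE.6140.3 was listed at 0 in all 5 WKY libraries, at 57.6 ± 11.7 in SHR (SD, n = 5) and at 58.8 ± 26.4 in neferine-treated SHR (SD, n = 6), with a limma adjusted p of 1.59e-09 for SHR against WKY. MERGE.16966.1 had a value of 0.421 ± 0.155 in WKY (SD, n = 5), 82.3 ± 20.2 in SHR (SD, n = 5) and 89 ± 7.54 with neferine (SD, n = 6). Its log2 fold change in SHR against WKY was 5.85 (SE 0.141, limma adjusted p 1.95e-13). Among the same rows, from which 1816 transcripts with a WKY mean of at least 0.5 are absent, the largest fall was that of MERGE.14292.23, with a log2 fold change of -5.72 (SE 0.611, limma adjusted p 1.99e-05). Its value was 94.7 ± 28.1 in WKY (SD, n = 5). It was listed at 0 in 4 SHR libraries and in all 6 neferine libraries, and at 15.2 in SHR 2.

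A total of 27 transcripts had a value of at least 1 in all 5 WKY libraries and were listed at 0 in all 5 SHR libraries, and 17 showed the opposite. Of the 126 ways to split these 10 libraries into 5 and 5, the other splits gave at most 4 such transcripts against 44 for the strains. All 17 transcripts present in SHR alone were rows of the neferine files, and each neferine library had a value of at least 1 for 16 or 17 of them. Only 3 of the 27 transcripts present in WKY alone were rows of the neferine files. No neferine library had a value of at least 1 for more than 1 of these 3. Transcripts present in SHR alone pass the filter before deposit by their SHR mean, so their presence as rows was largely set by it. The contrast in row presence is therefore partly built in.

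The second comparison asked what neferine changed in the hypertensive heart. limma called 1 of 24577 transcripts at an adjusted p under 0.05, and it was lower with neferine. At an unadjusted p under 0.05, 1446 transcripts passed (5.88%), against 1229 expected with no difference. The next smallest adjusted p was 0.0588. The 6 neferine and 5 SHR libraries did not overlap for 0.517% of transcripts, against 0.433% by chance. The median standard error of a log2 fold change was 0.23. For 68.6% of the transcripts the 95% confidence interval of the fold change lay within 2-fold in either direction. This holds for the value + 1, so at low values a larger change of the value itself can lie within that bound. In simulated data with the spread of these libraries, 100 transcripts were changed by 1 on the log2 scale and 100 by 2. The same test of neferine against SHR recovered 67% and 84% of these. The changed transcripts were drawn from those with a mean log2(value + 1) of at least 2. Recovery at lower values, or with fewer changed transcripts, was not simulated. The neferine files had a different set of rows from the SHR files, and whether both sets were quantified together is not given in the sources used here, so a difference between the sets of files would coincide with the treatment.

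**Figure D2:**
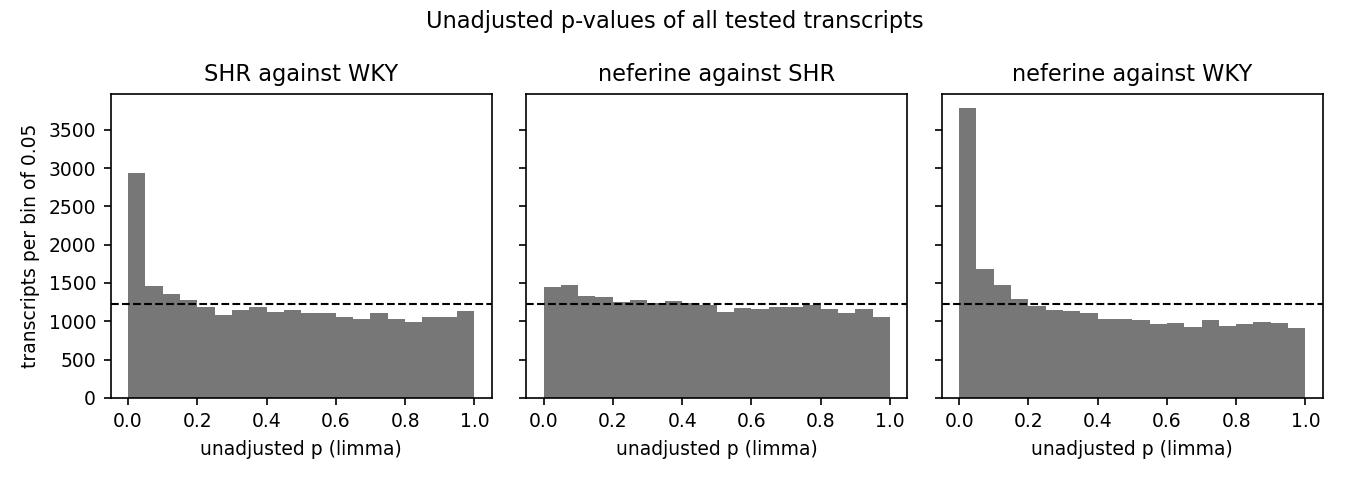
Unadjusted limma p-values of 24577 transcripts in each of the 3 comparisons, in bins of 0.05. The dashed line is the number per bin with no difference (1229), and the first bin holds 2935, 1446 and 3786 transcripts from left to right.

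The transcript that passed was MERGE.5947.1, with a log2 fold change of -5.83 in neferine-treated against untreated SHR (SE 0.271, limma adjusted p 2.78e-08). Its value was 92.2 ± 23.9 in SHR (SD, n = 5) and 67.7 ± 10.1 in WKY (SD, n = 5). With neferine it was 2.35, 0.546, 0.757 and 0.819 in libraries 1, 2, 3 and 6 and was listed at 0 in libraries 4 and 5. It did not pass between SHR and WKY (log2 fold change 0.41, limma adjusted p 0.661). It is 1 of 51 assembled transcripts of its locus that were in both sets of files. Of the 43 others that were tested, 24 were lower and 19 higher with neferine, and none passed the adjusted threshold (smallest limma adjusted p 0.061). The WKY and SHR files held 56 rows of the locus and the neferine files 51, and the 5 further rows added at most 20.1 to the sum of a SHR library. The sum over all rows of the locus in a file was 3580 ± 289 in SHR (SD, n = 5) and ranged from 419 to 3390 among the 6 neferine libraries. The log2 sum was lower with neferine by a mean difference of -1.27, which did not pass a two-sided exact permutation test (p = 0.0714, 462 splits), with the same difference and p over the shared rows.

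**Figure D3:**
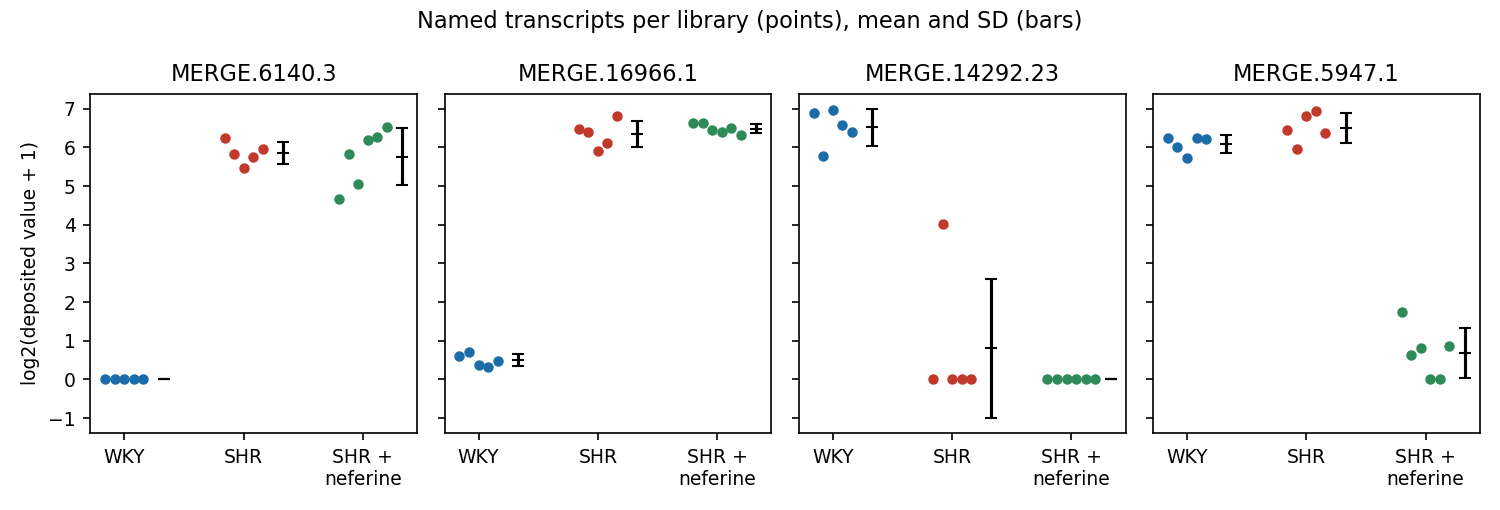
Values of the 4 named transcripts in each library as log2(value + 1), with the mean and SD of each group beside the points. MERGE.6140.3 and MERGE.16966.1 are high in both SHR groups, MERGE.14292.23 is high in WKY, and MERGE.5947.1 is low in the neferine group.

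The third comparison asked what difference from the control strain remained under neferine. limma called 1008 of 24577 transcripts between neferine-treated SHR and WKY, 646 higher and 362 lower in the treated rats, and 3786 passed at an unadjusted p under 0.05. Of the 720 transcripts called between SHR and WKY, 585 were also called here, all in the same direction, and 715 (99.3%) had the same sign. Independent lists of these sizes would share 12.2 higher and 3.77 lower transcripts. Both comparisons use the same WKY libraries. Unchanged groups simulated 50 times shared 0 calls, but groups without a difference leave few calls to share. That 0 therefore does not tell how many shared calls the common WKY libraries add where the strains differ. The 99.3% with the same sign were not set against a reference. When the WKY libraries were split so that each comparison had its own, a median of 306 calls were shared over 20 fits. The covariance of the fold changes across transcripts was 0.231, against a median of 0.0845 in the simulations.

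The last comparison asked whether neferine moved transcripts back that differ between the strains. No transcript passed both limma tests at an adjusted p under 0.05, in opposite directions or in the same direction (0 transcripts). At an unadjusted p under 0.05 in both, 306 transcripts moved in opposite directions and 48 in the same direction. The untreated SHR libraries enter both comparisons with opposite signs, and unchanged groups simulated 50 times gave a median of 284 opposite pairs (252 to 336) and 2 same-direction pairs (0 to 6). The SHR libraries were also split in 2 and 3 so that each comparison had its own. Over 20 fits the median was 84 opposite transcripts (73 to 110) and 122 same-direction transcripts (74 to 526). The same-direction count thus depended strongly on how the SHR libraries were divided. The correlation of the fold changes across transcripts, which are not independent replicates, was -0.347, against a median of -0.524 in the simulations. With split SHR libraries its median was 0.0179 (-0.0104 to 0.0959). The covariance was -0.0789, against a simulated median of -0.0856 (-0.0911 to -0.0764). The simulated groups held no strain difference, and their transcripts varied independently. A gap between observed and simulated counts or correlations therefore does not by itself show an effect of neferine, nor the lack of one.

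**Figure D4:**
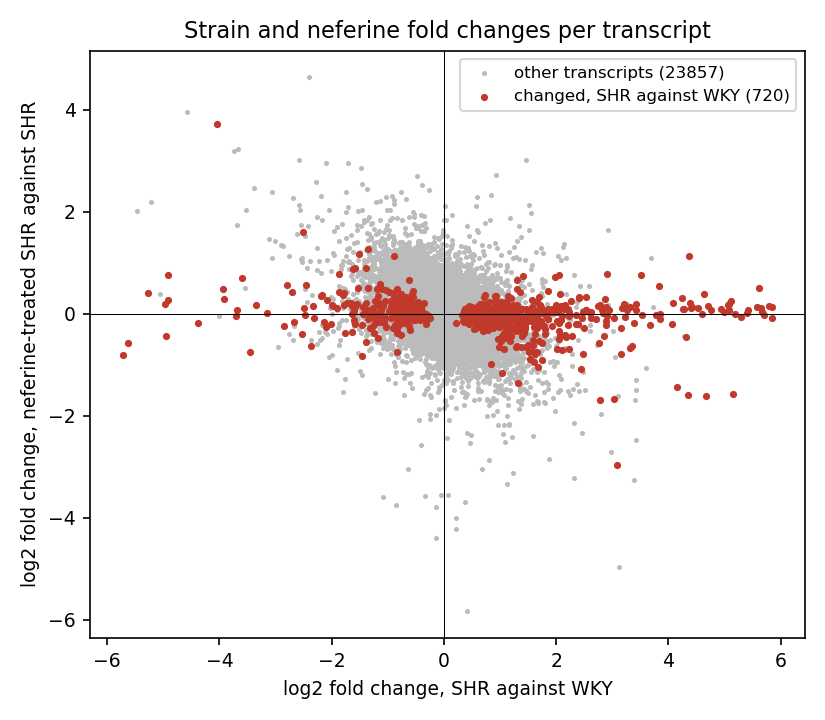
Log2 fold change of neferine-treated against untreated SHR (vertical axis) against that of SHR against WKY (horizontal axis), 1 point per transcript, with the 720 transcripts called between the strains in red. Because both axes use the same SHR libraries, a negative slope arises with no effect of neferine.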

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

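The tests of an exchange of animals, of the share of assembled transcripts, of the neferine transcript and of the row sets were chosen after the results were seen. The tests of abundant transcripts and of scale were written down before their results.

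Among 33 groups of library values examined, 2 held a library far from the rest, and chance alone gives about 1 in 20. MERGE.14292.23 had a value of 15.2 in SHR 2 and was listed at 0 in the other 4 SHR libraries. Without SHR 2 the SHR group is listed at 0 throughout, so no fold is given for that case, and the transcript was still called lower in SHR (limma adjusted p 8.35e-12; 8.35e-12 to 0.00133 over its 18 alternatives). MERGE.5947.1 had a value of 2.35 in neferine library 1 and at most 0.819 in the other 5. Without that library its log2 fold change was -6.04 in place of -5.83. Outside the rows that were compared, 1 transcript of the 1556 listed in the neferine files alone, ENSRNOT00000091789, had a value of at least 1 in all 6 neferine libraries (1.28 to 2.88). It was chosen after its values were seen, and it has no value in the WKY and SHR files to compare with.

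Within the groups, the libraries differed along one direction that the labels do not explain. The first component of the residuals held 12% of their variance. WKY 1, WKY 3, SHR 3 and SHR 4 had scores of -0.295, -0.345, -0.462 and -0.305, the other WKY and SHR libraries had scores from 0.0662 to 0.396, and the neferine libraries lay from -0.161 to 0.143. A few abundant transcripts were not the cause, since scores without the 50 most abundant transcripts had an absolute correlation of 0.998 with the first scores. A single scale factor per library was not either, since this correlation was 0.999 after median-of-ratios scaling. Those factors ran only from 0.958 to 1.11, so the scaling could move the scores little. Scale differences that depend on abundance were not tested. An exchange of animals between the strains is argued against, because each of these 4 libraries lay nearer to its own strain at 81.8% or more of the strain-dependent transcripts found without it. That stayed short of the 90% set for the test in 3 of the 4 libraries, but libraries outside the pattern fell short as well (SHR 2 at 83%). The share of a library's values in assembled transcripts, without the 50 most abundant, followed the scores over 16 libraries. Pearson's r was 0.761 (permutation p 0.00052, adjusted over 4 relations 0.00104) and Spearman's rho 0.815 (permutation p 0.00021, adjusted 0.00042), and r was 0.804 without SHR 2 and SHR 6. The sum of deposited values had r of -0.935 and rho of -0.935 (permutation p 1e-05 for both, the smallest that the permutations can give, adjusted 4e-05), and r was -0.923 without WKY 6 and SHR 3. The number of rows at 0 had r of -0.206 (permutation p 0.444, adjusted 0.592) and rho of -0.171 (permutation p 0.528, adjusted 0.704), but r was -0.514 without neferine 5 and 6, so whether it follows the scores rests on those libraries. The share of the 10 most abundant transcripts had r of 0.0332 (permutation p 0.903, adjusted 0.903) and rho of -0.0941 (permutation p 0.733, adjusted 0.733), and r was 0.225 without WKY 6 and SHR 2. All 4 measures come from the same values as the scores, so their correlations are not independent support for a cause. A difference in RNA or library composition between preparations is a candidate explanation. No label records preparation, and no biological explanation was tested.

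The neferine transcript MERGE.5947.1 belongs to a locus with 51 assembled transcripts in both sets of files. A lower output of the whole locus is argued against as the sole cause, because the transcript held at most 0.552% of the locus sum in the neferine libraries, against 1.9% to 3.33% in SHR and 1.25% to 2.15% in WKY. Values assigned to other transcripts of the locus would raise the sum of those others. Their mean sum was instead lower with neferine, by a difference of -1443, but the log2 locus sum did not pass its exact permutation test (p = 0.0714). The transcript's own mean fell by 91.4, less than the SD of 289 of the locus sum among SHR libraries, so a rise of that size would not show and this explanation stays open. Of 43 other tested transcripts of the locus, 24 were lower and 19 higher with neferine, and none passed the adjusted threshold (smallest limma adjusted p 0.061). At an unadjusted p under 0.05, 9 were lower and 1 higher, and the same 9 were below 0.01. As many below 0.01 in one direction were found in 1 of 100 splits, the real one, and the highest other split had 6, but the locus had been chosen for its call in the real split. The sums over these 9 were 47.6, 307, 741, 15.5, 8.03 and 39.7 in neferine libraries 1 to 6, against 556 to 1361 in SHR. In library 3 they thus lay within the SHR range while MERGE.5947.1 was at 0.757. Transcripts that switch on and off between libraries stay open as a cause of its fall. Of 1151 transcripts with a mean above 50, 97 (8.43%) had a highest library over 50 times the lowest (1 added to each). This was taken over all 16 libraries, so the 97 include transcripts that differ between groups, such as MERGE.5947.1 itself and MERGE.16966.1. The share is therefore not a rate of switching regardless of group. Among 100 splits of the 11 SHR and neferine libraries, the real one included, 3 held an adjusted p as small as 2.78e-08, and the smallest in another split was 4.24e-10. Neferine files quantified apart from the others cannot be told apart from neferine, since the sets of files coincide with the groups. There was 1 transcript that separated all 6 neferine libraries from all 10 others by more than 4 times plus 2 units, and it was this one. An effect of neferine on the transcript is among the open explanations.

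On the rows shared by all files, 64.4% of the calls between the strains were higher in SHR. Rows left out of the neferine files before deposit are a candidate cause. With all rows of the WKY and SHR files the share was 52.6%, and for the same libraries on the shared rows it was 62.2%. Calls lower in SHR were 304 with all rows and 194 with the shared rows, and calls higher in SHR were 337 and 319. Of the 1882 missing rows, 1788 had a SHR mean under 0.5, so their absence favours calls higher in SHR by construction. Of the missing rows, 93 had a value of at least 1 in all 5 WKY libraries. A strain difference that raises more transcripts than it lowers stays open and was not tested.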

How the results depend on the processing

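Scalings, the residual component, robust moderation, locus sums, other rows and subsets of libraries were chosen after the data were seen.

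For SHR against WKY, 20 of 25 alternatives gave a count within 1.5 times 720. Stricter thresholds gave 422 (log2 fold change of at least 1) and 426 (adjusted p under 0.01), by construction. Locus sums gave 440 of 8664 tested. Without WKY 1 and 3 and SHR 3 and 4 the count was 420. Those 4 alone shared 82 of 183 calls with the 720, and the other 6 WKY and SHR libraries 304 of 559. Leaving out 1 library gave 572 to 684. With the residual component as a covariate it was 946, and 718 of the 720 remained. The share higher in SHR was 64.4%, 62.2% for WKY and SHR alone on the same rows, and 52.6% with all their rows. There, 484 of 641 calls were in the 720. Of 100 splits of the 10 libraries, the real one included, 2 gave as many calls, so few reach 720. The highest other split gave 930 and set WKY 1, 3 and 4 with SHR 3 and 4 against the rest. In place of WKY 4, SHR 6 gave 448, SHR 2 gave 4, and WKY 6 or SHR 1 gave 0. Setting WKY 1 and 3 and SHR 3 and 4 apart gave many calls in some splits only.

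For neferine against SHR, 17 of 24 alternatives gave 1 call. The fit of these groups alone gave 3, and locus sums gave 0 of 8664 by limma with 477 at an unadjusted p under 0.05. The cause of either change was not tested. Leaving out 1 library gave 1 to 7: 7 without neferine 3, 3 without SHR 2, and 2 without SHR 1, SHR 4 or SHR 6. Of 100 splits of the 11 libraries, 44 gave at least 1 call and the highest other gave 6, so chance cannot be excluded for this count. MERGE.5947.1 was called in all 20 alternatives that tested it, with adjusted p from 2.65e-09 to 0.000295.

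For neferine against WKY, 20 of 24 alternatives were within 1.5 times 1008. The others gave 510 (log2 fold change of at least 1), 527 (adjusted p under 0.01), 541 (locus sums, of 8664) and 619 (without WKY 1 and 3 and SHR 3 and 4). The locus sums again count assembled loci alone, so 541 is not comparable with 1008. Leaving out 1 library gave 719 to 1033. Of 100 splits, only the real one gave as many calls (highest other 600), but file sets coincide with these groups.

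For transcripts moved back by neferine, 20 of 27 alternatives gave 0. An unadjusted p under 0.05 in both gave 306. With split SHR libraries the highest of 20 fits gave 2. Leaving out 1 library gave 0 to 2: 2 without SHR 2 or neferine 3, and 1 without WKY 3, WKY 6 or SHR 6. The 3 transcripts named for the strains kept their direction and passed in each alternative that tested them, but fold sizes depend on the pseudocount: at 0.1 the log2 fold changes were 7.32 for MERGE.16966.1, -8.38 for MERGE.14292.23 and, with neferine, -7.54 for MERGE.5947.1. No fold is given for MERGE.6140.3, listed at 0 in all WKY libraries, whose fitted value is set by the pseudocount.

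Animal numbers did not pair the libraries. Residuals of 14 same-numbered pairs correlated between -0.073 and 0.12, 1 pair passed 0.1, and 3 of 16 libraries correlated best with their own number. With the number as a block, the counts were 500, 1 and 727 in the order above, and 0 for transcripts moved back.

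Not run for want of counts: the quasi-likelihood, Wald and voom tests, their size factors and filters, and the surrogate variable. Gene list tests and genes fixed by symbol were not run for want of names. The limit set by depth is unknown.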

Other observations

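The first test was written down before its own result was seen, but after the fold changes of all comparisons had been examined. The test of directions within loci, on all rows of the WKY and SHR files, was chosen after the same test on shared rows had been seen.

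A movement of the treated hearts towards the control strain was tested along the strain difference itself. Transcripts called between WKY and SHR without 1 SHR library (183 to 247 of them) set an axis from 0, the WKY mean, to 1, the mean of the other 4 SHR libraries. The held-out SHR libraries scored 0.854 ± 0.0839 (SD, n = 5) and the neferine libraries 0.908 ± 0.0185 (SD, n = 6). The difference of 0.0537 points away from WKY and did not pass a two-sided exact permutation test (p = 0.175). Each neferine score was a mean over the 5 axes, while each SHR score came from 1 axis. The scores are therefore not strictly exchangeable, and this p-value is approximate. The prediction was a difference of -0.1 or lower, so a movement of that size towards WKY was not seen in these libraries.

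A second hypothesis was that the strains use different assembled transcripts of the same loci. Transcripts present in WKY alone are mostly missing from the shared rows, so it was tested on all rows of the WKY and SHR files. There, 431 assembled transcripts were called between SHR and WKY in 359 loci, of which 37 held at least 2 calls. Calls in both directions were found in 17 loci. With the directions of the calls shuffled 10000 times, the median was 22 (11 to 31), and a share of 0.967 of the shuffles gave as many or more. On the shared rows it was 13 loci against a median of 18. Calls in both directions were thus no more frequent than with shuffled directions. The shuffle treats directions within a locus as unrelated, so it does not give the number to be found without a shift between transcripts. The test therefore does not decide the hypothesis. At the 17 loci, transcripts of the same locus were called in opposite directions.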
